A study of Drosophila melanogaster with 4 samples.

How the data were processed

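RNA from ovaries of 7-day-old flies kept at 25 °C was sequenced in 4 libraries, 2 per genotype, with a strand-specific Agilent SureSelect kit on an Illumina NextSeq sequencer, as single-end reads of 75 bp, per the labels' protocols. Per the submitters' processing notes, bcl2fastq 2.0 and Bowtie 0.12.2 were used, and the builds BDGP6 and mm8 are named without a role. Which tool computed the values, which test the authors used and whether counting used strand are not given in the sources used here. The deposited coordinates match a BDGP6 annotation, in which 17171 of the 17475 gene identifiers (98.3%) were found, 99.8% of these on the same chromosome. After 1 was added to the deposited starts, which count from 0, 70.0% had the same start; some other loci are merged from overlapping genes.

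The authors deposited FPKM values per library, per the file headers, in which 0.0001 stands for 0. The authors also deposited FPKM per genotype, the ratio of wh7 to control, its log2 value, and a p-value and q-value per gene, per the file headers. The genotype values equal the mean of the 2 libraries within 1% except for mt:lrRNA, whose control value is 0.0001 in the authors' deposited table although its libraries average 29398 FPKM, so the authors' ratio for that gene was not used. Further deposited tables hold 11 ribosomal genes (4 marked significant), 1589 genes changed at least 2-fold (1468 higher and 121 lower, 1246 of them marked significant, largest q 0.228), and enrichment of 318 gene ontology terms (51 under a Benjamini adjusted p-value of 0.05) and 17 KEGG pathways (4 under it), with the fold enrichment the authors deposited. The leading term in the authors' deposited table was integral component of plasma membrane (113 genes, 2.15-fold enriched, Benjamini adjusted p = 5.13e-13).

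Groups were taken from the source names. The description fields name another experiment, against tkv, and were not used; levels of wuho were checked instead. All 4 per-library columns were used, and 0 such columns were left out. No read counts are given, so no count model was used. Low values below 0.1 FPKM fell on ratios of whole reads between libraries for 77.8% of 667 genes (control 2 with control 1), 75.5% of 355 (wh7 1) and 76.9% of 338 (wh7 2), within 0.001 on the log2 scale. From genes with a single annotated transcript, 1 read in 1 kb was worth about 0.0493, 0.0523, 0.0524 and 0.0517 FPKM in control 1, control 2, wh7 1 and wh7 2, which may already include the authors' scaling between libraries. The whole-read ratios put 1 read at 3.45% more FPKM in control 2 than in control 1, 1.03% less in wh7 1 and 2.38% more in wh7 2. These 2 estimates differ, for wh7 1 in direction, so both are approximate. A value of 1 FPKM in a 1-kb transcript thus rests on about 20 reads, and values of low genes are imprecise.

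Genes with at least 1 FPKM in at least 2 libraries were kept (8580 genes, 8022 of them protein-coding). A gene under 1 FPKM in both controls can pass this filter only through the wh7 libraries, which favours rises among genes and list members of low control expression. limma (3.58.1, in R 4.3.3) was fitted to log2(FPKM + 1) with a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every adjusted p of a gene in the text is limma's. Fold changes in the text are ratios of mean FPKM; log2 changes are differences on the log2(FPKM + 1) scale and understate the change of low genes. With 2 libraries against 2, an exact two-sided permutation test of 1 gene cannot pass the threshold, since at best 33.3% of splits are as extreme, so the adjusted p rests on the spread pooled across genes (prior degrees of freedom 2.69).

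Before the data were examined, 31 gene lists of 452 symbols were fixed, of which 3 symbols (closca, mei-217 and SOLO) were not matched and 20 were matched through RefSeq synonyms. Lists with at least 3 tested members (30) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists. With an estimated correlation, camera rests on the residual degrees of freedom, which are few with 2 libraries per group. A call lost there decides little. The rule for named genes, also fixed before, took wuho, the 12 largest rises and the 12 largest falls among called genes without overlap of the groups and at least 5 FPKM in the higher group, and up to 4 called members of each list with the largest change, or 2 members with the highest expression where none was called, giving 120 genes, 116 of them called. Genes named outside this rule are said to have been chosen after their values were seen.

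The test was tried on simulated data with 8580 genes. With 200 genes changed, 49% of those changed 2-fold and 88% of those changed 4-fold were recovered, with 6 false calls among 143. With 40% of genes changed, 89.2% and 98.4% were recovered, with 2.37% false calls among 3296. A shifted list was found by camera and 0 of 29 other lists were called. The simulated genes varied independently of each other, unlike real list members (estimated correlation 0.884 in the muscle list). The simulation therefore does not show how often camera calls lists of correlated genes falsely, and its share of false gene calls rests on the same independence. Every simulated change was 2-fold or 4-fold, and the variances were drawn from limma's own fitted trend and prior. In the data only 1349 of 3403 calls reached 2-fold, so the simulated shares do not carry over to the real calls.

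Alternatives fixed before the data were examined were the replicate number as a block, no filter, a filter of 5 FPKM, quantile normalization, median ratio scaling, pseudocounts of 0.1 and 5, limma without the trend, camera with an estimated correlation, fry, the authors' own calls and leaving out each library. A crossed pairing, protein-coding genes only and a fit without the marker lists were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A check of GC content or of reads from other organisms was not made, since no reads were used.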

Results

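Ovaries of 7-day-old adult Drosophila melanogaster were profiled by RNA sequencing in 4 libraries, 2 from control flies of w1118, a white-eyed laboratory strain, and 2 from flies carrying wh7, a mutant allele of wuho, in the same strain background per the labels. The wuho gene encodes a WD-repeat protein, the fly counterpart of WDR4 and of yeast Trm82, which is a subunit of the enzyme that methylates guanosine in tRNA. The comparison asks which transcripts differ between mutant and control ovaries. The values are FPKM per library, with sums of 682414 and 757802 in the controls and of 723860 and 753291 in the wh7 libraries. Total read numbers are not given in the sources used here. About 75.5% to 77.8% of the low values compared between libraries fell on steps of whole reads. In a transcript of 1 kb, 1 FPKM stood for about 19.1 to 20.3 reads on the authors' scale. Of 17475 genes in the table, 6735 and 6555 were at the floor that stands for 0 in the controls and 4673 and 4724 in the wh7 libraries. Across genes, which are not independent replicates, the 2 controls correlated at r = 0.979, the 2 wh7 libraries at 0.968 and libraries of different genotype at 0.890 to 0.933.

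The mutated gene was examined first, because the labels conflict. The strain field gives w1118 for all 4 samples, spelled w118 in the control titles, and the genotype fields give wild type or wh7. Source names give control or wh7 ovary, whereas the description field of each sample names an experiment with RNA interference against tkv, a receptor gene of the BMP pathway. wuho (FBgn0029857) lies on the plus strand of chromosome X at 6288100 to 6289562 in BDGP6. It was at 24.7 and 25.4 FPKM in the controls and at 0.832 and 0.646 FPKM in the wh7 libraries, so that wh7 held 2.95% of the control mean. The change was -3.91 ± 0.152 (SE) on the log2(FPKM + 1) scale with a limma adjusted p of 0.00245, while the authors' deposited table gave wuho a q of 0.302. tkv was not lower in the libraries labelled wh7, at 56.4 ± 0.919 FPKM against 48.7 ± 1.05 FPKM in controls (SD, n = 2), with a limma adjusted p of 0.0898. Top3beta (FBgn0026015), a topoisomerase gene singled out after its values were seen, lies next to wuho on the minus strand at 6284138 to 6287990. It fell 4.98-fold from 44.3 ± 0.939 to 8.90 ± 0.158 FPKM (SD, n = 2; limma adjusted p = 0.00281). Rpt4, likewise singled out afterwards, is a proteasome gene that shares 93 exon bases with the end of wuho on the opposite strand. It was at 136 ± 7.33 and 155 ± 18.1 FPKM, with a limma adjusted p of 0.238. The authors' table gives wuho and Rpt4 a single merged locus, and whether their counting used strand is not given in the sources used here.

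**Figure D1:**
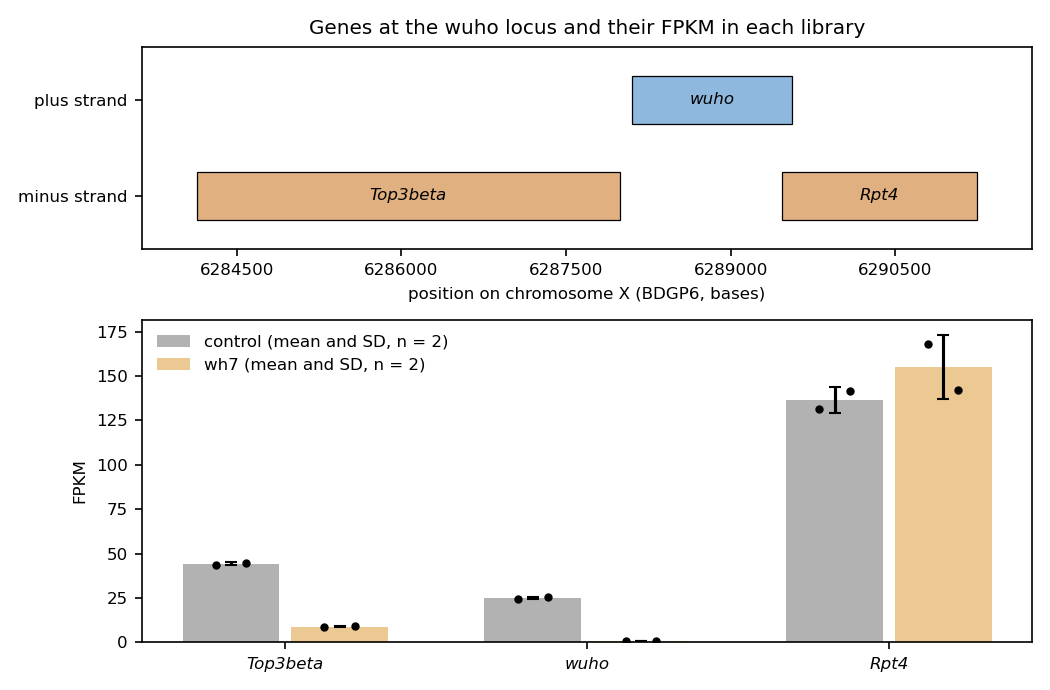
The upper panel maps Top3beta, wuho and Rpt4 on chromosome X by strand (BDGP6, bases), and the lower panel plots their FPKM per library (points) with the group mean and SD (bars, n = 2). Control means were 44.3 FPKM for Top3beta, 25.0 for wuho and 136 for Rpt4, and wh7 means were 8.90, 0.739 and 155.

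The wh7 libraries carried higher levels of muscle, hemocyte, follicle cell and immune transcripts and lower levels of cell cycle and maternal patterning transcripts. These 6 lists were called by camera with a preset correlation, and each call was lost with an estimated one (adjusted p = 0.601 to 0.698 with an estimated correlation). That form of camera has little power with so few libraries, so a lost call alone does not tell low power from correlation between genes. The estimated correlations were 0.884 for muscle, 0.684 for cell cycle, 0.236 for follicle cell and 0.0468 for hemocyte genes. These lie above the preset 0.01, so correlation may have helped to end those calls. For antimicrobial peptide and maternal patterning genes the estimated correlations, -0.105 and -0.000294, lay under the preset 0.01, yet their calls were lost too. The rotation test fry called all of the 6 lists but the cell cycle list (adjusted p = 0.0826). Of 8580 genes tested with limma on log2(FPKM + 1), a scale that understates the change of low genes, 3403 (39.7%) changed at an adjusted p under 0.05, 1820 higher and 1583 lower. Large changes went mostly upward, with 1257 genes at least 2-fold higher and 92 at least 2-fold lower. In 6603 tested genes (77.0%, where chance gives 33.3%) the 2 groups did not overlap, which included all 3403 calls. The authors' deposited table marked 1660 genes as significant, 1263 higher and 397 lower. Of the 1464 of these tested here, 1360 were called in the same direction and 0 in the opposite one. Conversely, 2043 of the 3403 calls here were not marked significant by the authors. The number of calls was 764 without control 1, 1565 without control 2, 2363 without wh7 1 and 1226 without wh7 2, and calls of at least 2-fold, 1349 in all, were 667, 1053, 860 and 591. The split also depended on scaling, with 53.5% of calls higher as deposited, 44.9% after quantile normalization and 71.2% after median ratio scaling, which moved the median of all genes by 0.10. Nothing in the labels says that the libraries came from separate groups of flies, so p-values measure only the spread between these samples, which may be technical.

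**Figure D2:**
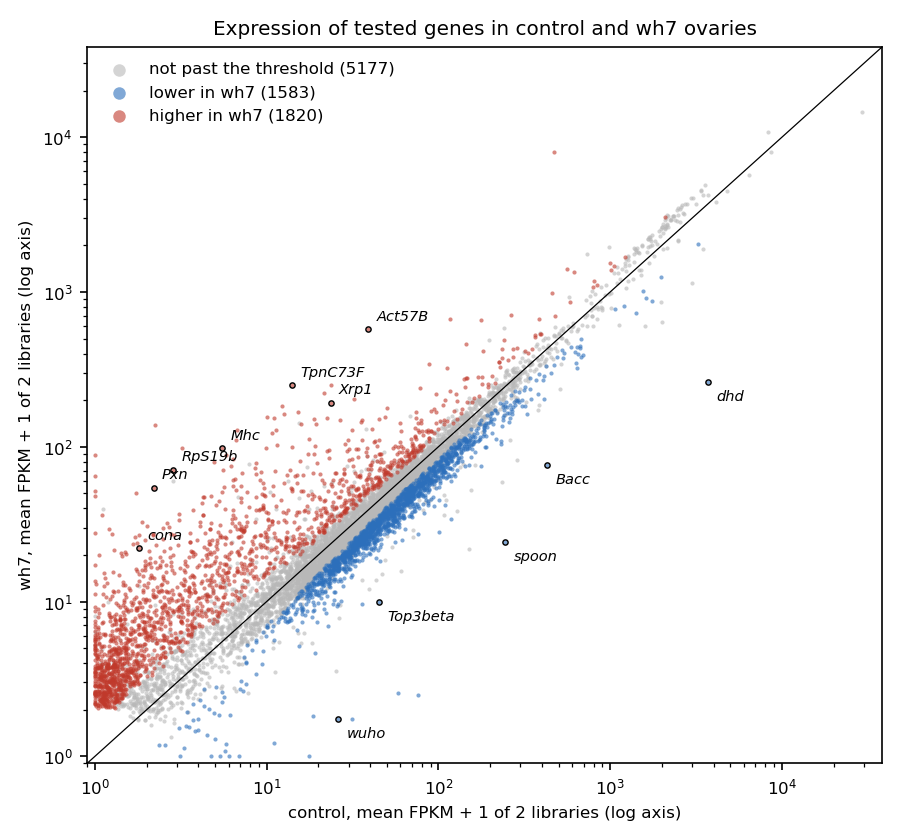
Mean FPKM + 1 of the 2 wh7 libraries (vertical, log axis) against that of the 2 control libraries (horizontal, log axis) for 8580 tested genes, with genes called higher in red, lower in blue and others in grey. The 1820 higher genes spread widely above the diagonal at low control values, and the 1583 lower genes lie close below it apart from a few such as dhd, spoon and wuho.

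Of the 12 largest rises, 7 were in non-coding RNAs or a pseudogene. snoRNA:Me18S-C1831, mir-4914, snRNA:U5:34A, mir-4940 and mir-33 were listed at 0 in both controls and at means of 86.8, 63.8, 50.9, 47.0 and 26.6 FPKM in wh7. FPKM of such short RNAs are uncertain because they divide by a short length. The deposited loci of mir-4914 (2725674 to 2739830) and mir-33 (19793935 to 19803427) are far longer than such RNAs. Whether reads of overlapping genes entered these values was not tested. The authors' q was 0.343 for snoRNA:Me18S-C1831, 0.395 for mir-4914, 0.410 for mir-4940 and 0.515 for mir-33, against 0.00160 for snRNA:U5:34A. The lincRNA CR40469 was listed at 0 and 2.45 FPKM in the controls and rose to 136 ± 26.2 FPKM (SD, n = 2), and the pseudogene CR44383 rose from 0.101 to 35.4 FPKM. The protein-coding genes were RpS19b, a ribosomal protein paralog (1.85 ± 0.213 to 70.2 ± 20.7 FPKM), Pxn, which encodes the extracellular matrix protein Peroxidasin (1.20 ± 0.571 to 53.3 ± 31.5 FPKM), and CG32368 (2.19 ± 2.80 to 97.7 ± 104 FPKM). They also held the immune-induced gene IM4 (0.204 to 28.5 FPKM) and the antifungal peptide gene Drs (0.732 ± 0.360 to 49.4 ± 44.6 FPKM). The authors' q was 0.477 for CR40469, 0.578 for CR44383, 0.603 for IM4 and 0.0621 for Drs, and 8.70e-04 for RpS19b, Pxn and CG32368. Where leaving out a library or another scaling ended a call, this is given in parentheses with the range of adjusted p over all alternatives. It did so for Drs (call lost without control 1, adjusted p 0.00148 to 0.0620) and CG32368 (call lost without control 1 or wh7 2, adjusted p 0.00706 to 0.122). With non-coding genes left out, a choice made after the values were seen, the 12 largest rises were joined by CG31313, CG7443, CG34331, CG16712 and the muscle genes TpnC73F, Mhc and Mlc2.

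The largest falls included CG42857 (74.9 ± 39.96 to 1.48 ± 0.264 FPKM; SD, n = 2), CG32699 (57.2 to 1.56 FPKM) and the lincRNA CR34335 (30.4 to 0.753 FPKM). They also included CG43954, which was at 15.2 and 17.9 FPKM in the controls and at the floor and 0.00142 FPKM in wh7. dhd, which encodes a thioredoxin of the female germline, fell 14.3-fold from 3724 ± 169.5 to 260.3 ± 78.1 FPKM (limma adjusted p = 0.00325). spoon, which encodes an A-kinase anchoring protein, fell 10.5-fold from 243 ± 10.3 to 23.3 ± 1.54 FPKM. Bacc fell 5.68-fold from 427 ± 27.5 to 75.3 ± 4.40 FPKM, CG4676 from 17.6 to 0.812 FPKM and CG13032 from 9.96 to 0.222 FPKM. CG30059 and snoRNA:Psi18S-1397 stood at 5.87 and 5.06 FPKM in the controls and were listed at 0 in both wh7 libraries. CG13032 and CG43954 are neighbours on chromosome 3L, at 16673964 to 16676264 and 16676406 to 16711677. These 11 genes and wuho kept their calls in every alternative fit that tested them. The authors' own calls did not include all of them. The authors' q was 0.302 for wuho, 0.620 for CR34335, 0.519 for CG43954 and 0.347 for snoRNA:Psi18S-1397. It was 8.70e-04 for each of the other genes.

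Muscle genes rose together in wh7. Of 17 tested members of the muscle sheath list 16 rose and 0 fell (17 and 0 adjusted over the list alone), and the median change was 3.58 on the log2 scale relative to the median of all tested genes. TpnC73F, a troponin C gene, rose 19.0-fold from 13.1 ± 1.36 to 249 ± 63.7 FPKM, and the muscle myosin heavy chain gene Mhc 21.7-fold from 4.48 ± 0.819 to 97.3 ± 56.6 FPKM. The myosin light chain gene Mlc2 rose 19.6-fold to 109.7 ± 48.3 FPKM and the tropomyosin gene Tm2 17.1-fold to 155 ± 54.6 FPKM (SD, n = 2). Tm1, singled out after its values were seen as the list member not called, was at 314 and 405 FPKM and missed the threshold over all genes (limma adjusted p = 0.0552). The list passed camera with a preset correlation (adjusted p = 7.08e-10) but not with an estimated one (adjusted p = 0.613 with an estimated correlation). Camera with a preset correlation called 13 of 30 lists. With an estimated correlation, a form with little power at 2 libraries per group, it called 0. There 0 lists had an unadjusted p under 0.05 and the smallest was 0.0560. The test fry, which tests each list by itself, called 10. Of the lists that camera called, fry missed the cell cycle, fat body, transferase and both ribosomal protein lists. It also called the spermatheca and testis lists, which camera did not.

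**Figure D3:**
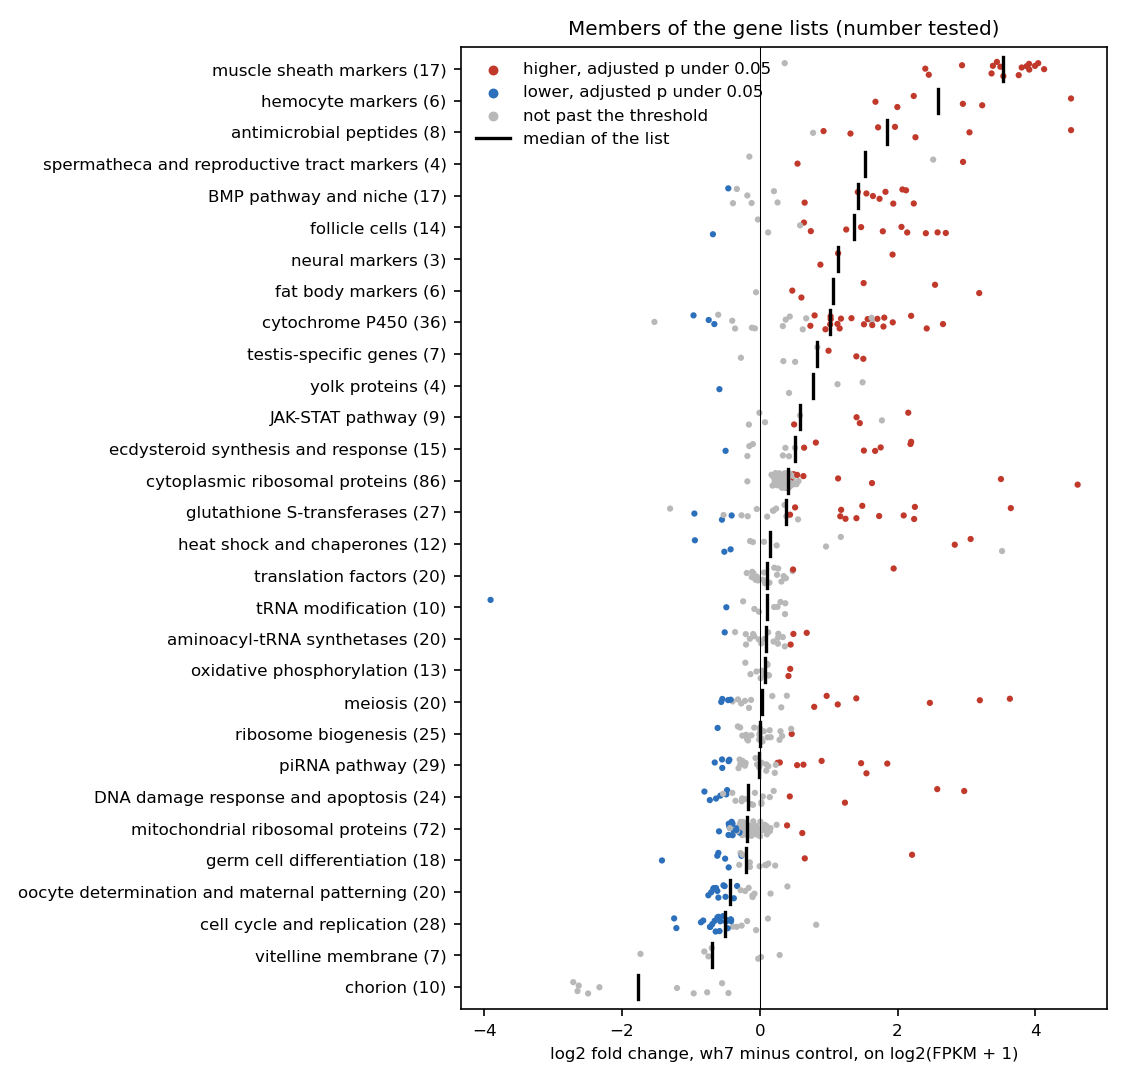
Log2 fold changes (wh7 minus control, on log2(FPKM + 1)) of the tested members of 30 gene lists, one line of points per list, with higher genes in red, lower genes in blue, others in grey and the median as a bar. Muscle sheath markers have the highest median, at 3.54, and chorion genes the lowest, at -1.76, with 0 of the 10 chorion genes past the threshold.

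Markers of other cell types were higher beside the muscle genes, and the list medians from here on are relative to the median of all tested genes. Hemocyte markers rose in 6 of 6 tested genes (6 and 0 adjusted over the list alone; median 2.63). They included Pxn, the scavenger receptor gene crq (10.5 ± 5.38 to 101 ± 4.10 FPKM; SD, n = 2), Nplp2 (5.58 ± 1.15 to 51.6 ± 21.4 FPKM) and vir-1 (8.79 to 47.2 FPKM; call lost without control 1, adjusted p 0.00127 to 0.05002). Of 6 tested fat body markers 5 rose and 0 fell (5 and 0 adjusted over the list alone; median 1.10, but 1.76 without control 2 and 0.54 without wh7 2). They were led by Obp99a (5.38 ± 0.0477 to 38.2 ± 17.6 FPKM) and the transferrin gene Tsf1 (0.112 to 10.2 FPKM; call lost without control 1, adjusted p 0.00307 to 0.0540). The lipoprotein gene Rfabg was a further riser (2.19 to 8.51 FPKM; call lost without control 1, control 2 or wh7 2 and after quantile normalization, adjusted p 0.0110 to 0.267). Of 11 neural markers 3 could be tested, each under 1 FPKM on average in the controls, and all 3 rose (3 and 0 adjusted over the list alone; median 1.18), elav from 0.942 to 6.39 FPKM and nrv3 from 0.836 to 3.04 FPKM (call lost without control 1 or control 2 and after quantile normalization, adjusted p 0.00742 to 0.923). Appl rose from 0.990 to 2.65 FPKM, with the direction of Appl reversed to -0.22 after quantile normalization (call lost without any 1 library and after quantile normalization, adjusted p 0.0170 to 0.386). With no filter on low values the neural median was 0.15. The fry test called hemocyte and neural markers but not fat body markers (fry adjusted p = 0.0967). Camera adjusted p were 7.92e-04 for hemocyte, 0.0260 for fat body and 0.0289 for neural markers. With an estimated correlation they were 0.601, 0.613 and 0.613. The neural list missed the threshold after quantile normalization (median 0.11, adjusted p = 0.585) and without control 2 (0.0539), in a range of 0.0137 to 0.585 over its alternatives.

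Of 19 gut markers 0 were expressed highly enough to be tested. Of 4 tested spermatheca and reproductive tract markers 2 rose and 0 fell (3 and 0 adjusted over the list alone; median 1.57, but 0.67 without wh7 1, 0.60 without wh7 2 and 0.46 with no filter; camera adjusted p = 0.145). CG18067 rose from 2.59 ± 0.252 to 26.9 ± 4.29 FPKM (SD, n = 2). Fmo-2 rose from 4.11 to 6.47 FPKM, with the direction of Fmo-2 reversed after quantile normalization (call lost without any 1 library and after quantile normalization, adjusted p 0.0221 to 0.237). Of 7 tested testis-specific genes 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0522), and the median of 0.88 was 0.055 after quantile normalization and 0.56 without wh7 2. Taf12L rose from 1.09 to 4.96 FPKM (call lost without control 1 and after quantile normalization, adjusted p 0.00670 to 0.280). sa was listed at 0 in the controls and at 1.65 FPKM in wh7 (call lost without control 1 or control 2 and after quantile normalization, adjusted p 0.00488 to 0.135). mia rose from 2.17 to 5.31 FPKM with its direction reversed after quantile normalization (call lost without any 1 library and after quantile normalization, adjusted p 0.0156 to 0.889). The camera adjusted p of the testis list ranged over 0.00971 to 0.775 over its alternatives. The fry test called both the testis and the spermatheca list (fry adjusted p = 0.0219 for each).

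Somatic cells of the ovary were represented by 4 lists. Of 14 tested follicle cell genes 10 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.40). The adhesion gene Fas3 rose 6.74-fold from 16.6 ± 5.26 to 112 ± 20.9 FPKM and the metalloproteinase gene Mmp2 6.92-fold to 30.1 ± 7.55 FPKM. The metalloproteinase inhibitor gene Timp rose 5.78-fold to 48.4 ± 9.68 FPKM and eya, a transcription cofactor gene, 4.74-fold to 37.9 ± 5.71 FPKM (SD, n = 2). The fallen member was cad, a homeobox gene, at 187 ± 6.39 and 117 ± 13.7 FPKM (call lost without control 1, adjusted p 0.00793 to 0.0740). Of 17 tested BMP pathway and niche genes 10 rose and 1 fell (11 and 1 adjusted over the list alone; median 1.47). That median was 0.66 after quantile normalization, 0.37 with a filter of 5 FPKM, 0.85 without wh7 1 and 0.93 without wh7 2. The transcription factor gene bab2 rose from 0.373 to 5.62 FPKM, fng, which encodes a modifier of Notch, 4.94-fold to 28.5 FPKM, the glypican gene dally 4.73-fold to 28.5 FPKM and the BMP ligand gene gbb 4.26-fold to 25.1 FPKM. The fallen member was Mad, a BMP signal transducer gene, at 66.1 and 47.8 FPKM (call lost without control 1, control 2 or wh7 2, adjusted p 0.0199 to 0.143); cad and Mad were singled out after their values were seen. Camera adjusted p were 8.69e-04 for follicle cells and 0.00620 for BMP and niche genes; adjusted p = 0.613 and 0.601 with an estimated correlation. In the same libraries the muscle sheath markers rose by a median of 3.58.

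The other 2 lists did not pass. Among 9 tested JAK-STAT genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.63, but 0.20 without wh7 1, 0.14 without wh7 2 and 0.19 with a filter of 5 FPKM; camera adjusted p = 0.0554). The feedback inhibitor gene Socs36E rose 5.54-fold to 22.8 ± 9.71 FPKM (SD, n = 2; call lost without control 1, adjusted p 0.00227 to 0.0511). chinmo rose from 0.439 to 2.94 FPKM (call lost without control 1 and after quantile normalization, adjusted p 0.00760 to 0.194). Among 15 tested ecdysteroid genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0522), and the median of 0.55 was 0.015 after quantile normalization and 0.33 without control 1. Cyp18a1, which inactivates ecdysone, rose 4.68-fold from 13.9 ± 5.79 to 65.1 ± 9.19 FPKM, and the synthesis gene phm 4.88-fold from 1.58 ± 0.144 to 7.70 ± 0.234 FPKM. The nuclear receptor gene Eip75B rose 3.27-fold from 28.2 ± 3.27 to 92.4 ± 11.3 FPKM and ImpL2 from 34.7 to 147 FPKM (call lost without wh7 2, adjusted p 0.00879 to 0.0656). The camera call of the ecdysteroid list came and went over its alternatives, at adjusted p of 0.0143 to 0.585, as did that of the JAK-STAT list, at 0.0385 to 0.302.

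Antimicrobial peptide genes were higher, and detoxification genes moved in both directions, more of them upward. Of 8 tested antimicrobial peptide genes 7 rose and 0 fell (8 and 0 adjusted over the list alone; median 1.88), among them Drs, Def (0.228 ± 0.00547 to 9.32 ± 2.80 FPKM; SD, n = 2) and AttC (0.0328 to 3.03 FPKM). Mtk was listed at 0 in the controls and at 3.89 FPKM in wh7. Only 1 of the 8 genes reached 1 FPKM on average in the controls. The others passed the filter only with help of a wh7 library, which favours rises, so the count of risen members says little of the list. The list median was 0.96 after quantile normalization. With no filter it was lower as well, though the camera call was kept. Of 36 tested cytochrome P450 genes 20 rose and 3 fell (22 and 4 adjusted over the list alone; median 1.07), led by Cyp6a20 (1.79 ± 0.420 to 16.9 ± 5.15 FPKM), Cyp6a13 (1.54 to 12.8 FPKM) and Cyp18a1. Of 27 tested glutathione S-transferase genes 12 rose and 3 fell (15 and 3 adjusted over the list alone; median 0.43). GstE10 rose from 0.133 to 14.2 FPKM, GstD2 from 3.50 to 20.8 FPKM, GstE3 from 1.47 to 10.6 FPKM and GstE9 from 2.95 to 15.8 FPKM. GstD1, singled out afterwards as the most expressed of them, fell from 1194 ± 54.0 to 816 ± 9.90 FPKM (call lost without wh7 1 or wh7 2, adjusted p 0.0155 to 0.0944). The fry test called the peptide and P450 lists but not the transferase list (fry adjusted p = 0.0541). Camera adjusted p were 6.88e-04, 0.00176 and 0.0117 for the peptide, P450 and transferase lists. With an estimated correlation they were 0.601, 0.613 and 0.698. The P450 list, at a median of 0.69 without wh7 1, missed the threshold after quantile normalization (median 0.13, adjusted p = 0.293, in a range of 0.00124 to 0.293 over its alternatives), and the transferase list with no filter on low values (0.215, in a range of 0.00248 to 0.215). Hemocyte and muscle sheath markers, at medians of 2.63 and 3.58, moved with these genes.

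Genes of the cell cycle and of DNA replication were lower. Of 28 tested members 0 rose and 20 fell (1 and 23 adjusted over the list alone; median -0.47). The replication licensing gene dup fell 2.38-fold from 175 ± 22.4 to 73.6 ± 11.2 FPKM (SD, n = 2). The origin recognition gene Orc1 fell 2.33-fold from 93.8 ± 13.7 to 40.2 ± 8.57 FPKM (call lost without control 1, adjusted p 0.00438 to 0.0608) and the cyclin gene CycB 1.76-fold from 1609 ± 142 to 913 ± 109.9 FPKM (call lost without control 1 or wh7 2, adjusted p 0.0122 to 0.0841). Of 20 tested oocyte determination and maternal patterning genes 0 rose and 12 fell (0 and 12 adjusted over the list alone; median -0.39). exu and swa, which act in the placing of bcd mRNA, fell 1.68-fold to 122 ± 17.1 FPKM (call lost without control 2 or wh7 2, adjusted p 0.00567 to 0.0691) and 1.598-fold to 148 ± 9.01 FPKM (call lost without control 1, adjusted p 0.00580 to 0.0540). bcd itself fell 1.64-fold to 30.3 ± 5.26 FPKM (call lost without control 1 or control 2, adjusted p 0.00813 to 0.111). Camera adjusted p were 8.73e-06 for the cell cycle list and 0.00153 for the maternal list; adjusted p = 0.698 and 0.601 with an estimated correlation. These falls stood beside a median rise of 3.58 in muscle sheath markers.

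Germline lists went both ways. Of 18 tested germ cell differentiation genes 2 rose and 6 fell (2 and 7 adjusted over the list alone; median -0.16, -0.16 to -0.10 with 1 library left out; camera adjusted p = 0.191). With no filter on low values this list passed camera (median -0.26, adjusted p = 0.0132, in a range of 0.0132 to 0.595 over its alternatives), and after quantile normalization its median was -0.034. bgcn, which acts in the differentiation of early germ cells, rose 19.3-fold from 0.247 ± 0.143 to 4.76 ± 0.268 FPKM (SD, n = 2), and CG32364 fell 2.87-fold from 24.9 ± 2.11 to 8.70 ± 0.732 FPKM. Of 20 tested meiosis genes 7 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.488), and the median of 0.07 turned to -0.21 after quantile normalization, -0.14 without wh7 1 and -0.14 without wh7 2. cona, a synaptonemal complex gene, rose 26.7-fold from 0.793 ± 0.358 to 21.1 ± 3.62 FPKM and the cohesion gene ord 39.0-fold from 0.274 ± 0.0709 to 10.7 ± 0.506 FPKM. CG32088 rose 23.7-fold to 6.03 ± 1.55 FPKM and CG8316 2.99-fold to 14.4 ± 2.44 FPKM. Of 29 tested piRNA pathway genes 8 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.879). The largest changes were in fs(1)Yb (1.06 to 6.44 FPKM), qin (8.21 to 25.98 FPKM), tj (29.2 to 81.0 FPKM) and piwi (93.6 ± 3.42 to 175 ± 0.898 FPKM), of which fs(1)Yb and tj act in somatic cells of the ovary. The median of the piRNA list was 0.032, 0.13 after quantile normalization and -0.073 with no filter on low values.

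Eggshell genes varied widely between libraries of one genotype. Of 10 tested chorion genes and 7 tested vitelline membrane genes, 0 passed the threshold of limma (0 also adjusted over the list alone), with medians of -1.72 and -0.65 and camera adjusted p of 0.379 and 0.699. Cp38 was at 593 and 5425 FPKM in the controls and at 1991 and 306 FPKM in wh7, Cp36 at 390.2 and 3571 against 1479.9 and 249 FPKM, and Vm34Ca at 1537 and 5373 against 2866 and 945 FPKM. Vm26Aa was at 2036 ± 1493 and 1889 ± 950.2 FPKM (SD, n = 2), and its direction reversed after quantile normalization. Without wh7 2 both list medians were positive, at 0.34 and 0.57, and without control 2 the vitelline median was 0.13. The chorion list passed camera without control 1 (adjusted p = 0.00971), without wh7 1 (0.0165) and with the crossed pairing as a block, an alternative chosen after seeing the data (3.41e-04), in a range of 3.41e-04 to 0.914 over its alternatives, and the vitelline list without control 1 (0.0476, in a range of 0.0476 to 0.865). Of 4 tested yolk protein genes 0 rose and 1 fell (0 and 1 adjusted over the list alone; median 0.82, but 0.15 without control 1 and 1.49 without control 2; camera adjusted p = 0.709). The fallen member was the yolk receptor gene yl, at 405 ± 78.5 and 267 ± 2.45 FPKM (call lost without control 2, wh7 1 or wh7 2 and after median ratio scaling, adjusted p 0.0213 to 0.0941).

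**Figure D4:**
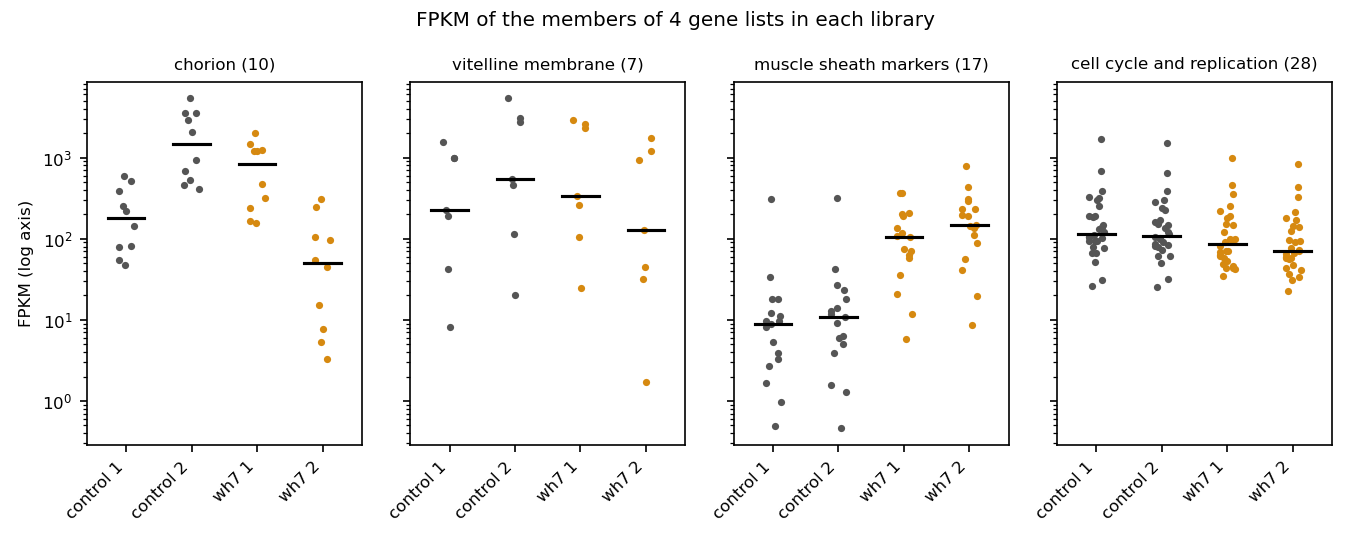
FPKM (log axis) of the tested members of 4 gene lists in each of the 4 libraries, one point per gene with the median as a bar, controls in grey and wh7 in orange. Chorion genes such as Cp38 range from 306 FPKM in wh7 2 to 5425 FPKM in control 2 with the genotypes interleaved, whereas muscle sheath genes such as Mhc, at 3.90 and 5.06 FPKM in controls and 57.2 and 137 FPKM in wh7, lie higher in both wh7 libraries.

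The authors' deposited tables include one of ribosomal genes, and the translation lists were examined with it. Of 86 tested cytoplasmic ribosomal protein genes 11 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.45, and 0.26 after quantile normalization), and 85 lay above 0. RpS19b rose 37.98-fold and RpS10a 15.8-fold from 2.08 ± 1.08 to 32.8 ± 1.65 FPKM. RpS5a rose 2.19-fold from 618 ± 99.7 to 1354 ± 70.5 FPKM (SD, n = 2) and RpL37b from 0.304 to 3.03 FPKM (call lost without control 1 and after quantile normalization, adjusted p 0.00534 to 0.114). Reads of such paralogs can be shared with a near-identical copy, and how the authors' counting treated them is not given in the sources used here. Of 72 tested mitochondrial ribosomal protein genes 2 rose and 15 fell (2 and 10 adjusted over the list alone; median -0.14). mRpL14 fell 1.52-fold to 43.5 FPKM (call lost without control 1 or control 2, adjusted p 0.00730 to 0.0617) and mRpL27 rose 1.55-fold to 61.3 FPKM (call lost without control 1, adjusted p 0.00593 to 0.0625). The fry test called neither the cytoplasmic nor the mitochondrial list (fry adjusted p = 0.111 and 0.235). Camera adjusted p were 5.09e-08 and 0.00176. With an estimated correlation they were 0.796 and 0.811. The mitochondrial list missed the threshold after quantile normalization (adjusted p = 0.543), without control 2 (0.0539) and without wh7 1 (0.165), in a range of 1.39e-07 to 0.543 over its alternatives. Its median was -0.01, -0.088 and -0.071 in these settings. Muscle sheath markers rose in the same libraries by a median of 3.58.

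Other translation lists did not pass. Of 10 tested tRNA modification genes 0 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.991), wuho and CG10050 (9.53 to 6.53 FPKM; call lost without any 1 library and after median ratio scaling, adjusted p 0.0167 to 0.183). The median of 0.14 (0.051 to 0.40 with 1 library left out) and the mean differed in sign. Of 25 ribosome biogenesis genes 1 rose and 1 fell (0 and 1 adjusted over the list alone; median 0.043, -0.043 to 0.23 with 1 library left out; camera adjusted p = 0.945). Non1 rose to 533 FPKM (call lost without control 1, wh7 1 or wh7 2, adjusted p 0.0154 to 0.140) and Nop60B fell to 297 FPKM (call lost without control 1, adjusted p 0.0105 to 0.0713). Of 20 translation factors 2 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.15, 0.12 to 0.29 with 1 library left out; camera adjusted p = 0.195). These were Thor, the fly 4E-BP repressor of translation (3.89-fold, 87.2 ± 8.12 to 339 ± 42.2 FPKM; SD, n = 2), and eIF-1A (366 to 512 FPKM; call lost without control 1 or wh7 2, adjusted p 0.0131 to 0.0969). Of 20 aminoacyl-tRNA synthetases 3 rose and 1 fell (2 and 1 adjusted over the list alone; median 0.14, 0.063 to 0.31 with 1 library left out; camera adjusted p = 0.454), with Aats-asn rising 1.61-fold to 117 FPKM (call lost without control 1, adjusted p 0.00804 to 0.0651). Of 13 oxidative phosphorylation genes 2 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.12, 0.064 to 0.21 with 1 library left out; camera adjusted p = 0.379). These were SdhC, which rose to 89.3 FPKM (call lost without control 1, control 2 or wh7 2, adjusted p 0.0103 to 0.114) and cype to 194 FPKM (call lost without control 1, control 2 or wh7 2, adjusted p 0.0128 to 0.122). Without wh7 1 the biogenesis, translation factor and synthetase lists passed camera (adjusted p = 0.0211, 0.0144 and 0.0245, in ranges of 0.0211 to 0.998, 0.0144 to 0.713 and 0.0245 to 0.990 over their alternatives). The translation factor list also passed with a filter of 5 FPKM (0.0428). Without wh7 2 the biogenesis median was -0.043. The phosphorylation and synthetase lists passed after quantile normalization (both 0.0466, the phosphorylation list in a range of 0.0466 to 0.955).

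The fixed lists of stress genes moved in both directions. Of 24 tested DNA damage and apoptosis genes 4 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.379), and the median of -0.13 and the mean differed in sign. Without wh7 2 the median was 0.038. Xrp1, a transcription factor gene of the response to ribosomal protein loss, rose 8.47-fold from 22.6 ± 0.347 to 191 ± 76.3 FPKM (SD, n = 2). The pro-apoptotic genes rpr and hid rose 24.4-fold to 7.07 ± 3.45 FPKM and 2.49-fold to 25.3 ± 0.848 FPKM. The helicase gene Blm fell 1.76-fold from 41.03 ± 2.42 to 23.2 ± 3.97 FPKM (call lost without control 1 or control 2, adjusted p 0.00793 to 0.0969). Of 12 tested heat shock and chaperone genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; median 0.19, -0.032 to 0.42 with 1 library left out; camera adjusted p = 0.881). stv, a co-chaperone gene with a role in muscle, rose from 3.73 ± 0.426 to 47.0 ± 38.7 FPKM (call lost without control 1 or control 2, adjusted p 8.01e-04 to 0.0943). Hsp67Bc rose from 1.04 ± 0.429 to 16.4 ± 13.97 FPKM (call lost without control 1 or control 2 and after quantile normalization, adjusted p 0.00274 to 0.117), while Hsp26 fell 1.92-fold from 1409 ± 20.4 to 734 ± 37.6 FPKM. The heat shock median was -0.032 without wh7 2, and the list passed camera without wh7 1 (adjusted p = 0.0144, in a range of 0.0144 to 0.996 over its alternatives).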

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

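Crossed pairing, protein-coding genes only and the fit without marker lists were chosen after seeing the data. In leave-one-out fits the lone library of a genotype is assumed to vary like the other genotype. Genes changed, 3403 as reported, ranged from 764 to 2363 when 1 library was left out, genes higher from 672 to 1127, genes lower from 87 to 1330, genes changed at least 2-fold from 591 to 1053 and lists changed from 12 to 17; fewer libraries leave less power, and beyond that the cause was not tested. Of the reported calls 741, 1425, 2041 and 1175 remained without control 1, control 2, wh7 1 and wh7 2. None of the 15 alternative fits turned the sign of a gene that it and the reported fit both called. The authors called 1660 genes. A filter of 5 FPKM, which tests fewer genes, gave 1087 higher and 754 at least 2-fold, and no filter gave 967 lower. Quantile normalization gave 1096 higher, median ratio scaling 844 lower, and a pseudocount of 5, which shrinks changes of low genes, 577 at least 2-fold. Camera with an estimated correlation called 0 lists and fry 10. The replicate number as a block gave 3624 genes changed, and the crossed pairing gave 2729 genes and 17 lists. The replicate deviations of the 2 genotypes correlated at -0.16, which gives no sign of pairing by number. Whether the libraries were prepared in pairs is not known. Of 116 named calls, 102 were kept after quantile normalization, 113 after median ratio scaling and 98 without a filter. With 1 library left out, 67 of 110 still tested were kept without control 1, 82 of 110 without control 2, 86 of 92 without wh7 1 and 68 of 92 without wh7 2.

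Directions reversed as follows, and the cause was not tested; list medians here are given before that of all genes was subtracted. After quantile normalization the log2 change was -0.16 for Vm26Aa, -0.28 for Fmo-2, -0.22 for Appl and -0.033 for mia, and list medians were -0.30 for meiosis, 0.043 for piRNA, -0.072 for ecdysteroid and -0.033 for testis-specific genes. The meiosis median was -0.21 with the filter of 5 FPKM. The piRNA median was 0.094 after median ratio scaling, but the median of all genes was then 0.062, so relative to it the piRNA list did not reverse. With 1 library left out, log2 changes ranged from -1.71 to 0.099 for Vm34Ca, -0.81 to 0.85 for Vm26Aa, -2.80 to 0.40 for Cp38 and -2.55 to 0.64 for Cp36. List medians then ranged from -0.046 to 0.32 for tRNA modification, -0.14 to 0.15 for ribosome biogenesis, -0.034 to 0.23 for aminoacyl-tRNA synthetases, -1.32 to 0.48 for vitelline membrane, -3.60 to 0.24 for chorion, -0.24 to 0.051 for meiosis, -0.029 to 0.032 for piRNA and -0.13 to 0.33 for heat shock genes. Relative to the median of all genes in the same setting, other sets of list medians changed sign. After quantile normalization the meiosis list did (-0.21), while testis-specific (0.055), ecdysteroid (0.015) and piRNA genes (0.13) stayed above 0. Without wh7 2 chorion (0.34), vitelline membrane (0.57), ribosome biogenesis (-0.043), meiosis (-0.14), heat shock (-0.032) and DNA damage genes (0.038) did, and tRNA modification (0.051) and synthetase genes (0.063) did not. Without control 2 the vitelline list did (0.13) and without wh7 1 the meiosis list (-0.14). With no filter meiosis (-0.036), piRNA (-0.073) and ribosome biogenesis genes (-0.063) changed sign, and with the filter of 5 FPKM meiosis genes (-0.11). Among called lists the relative median became 0.59 for BMP, 0.62 for fat body, 0.15 for neural, 1.09 for antimicrobial, 0.38 for P450, 0.23 for transferase and -0.25 for mitochondrial ribosomal genes with no filter; 3.15 for antimicrobial and -0.076 for mitochondrial ribosomal genes with the filter of 5 FPKM; 0.72 for BMP, 0.50 for neural, 0.79 for antimicrobial and 0.45 for P450 genes with a pseudocount of 5; and 1.79 for neural, 3.84 for antimicrobial and 1.66 for P450 genes with one of 0.1. About 20 reads stand behind 1 FPKM in 1 kb, which limits changes among low genes.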

Other observations

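The groups and the tests of muscle and follicle medians, of the muscle list and of the X neighbours in this part, and the reading of the fat body test, were chosen only after the result was seen. Basement membrane genes, which encode the sheet of matrix around ovarioles and muscle, were called higher in 10 of 10 tested members, with a median of 2.02 on the log2 scale relative to all tested genes (camera unadjusted p = 7.73e-07, and unadjusted p = 0.221 with an estimated correlation). LanB1, a laminin gene, rose from 18.2 ± 2.95 to 99.8 ± 2.99 FPKM, the perlecan gene trol from 30.4 ± 7.23 to 127 ± 24.5 FPKM, and Ppn, the Papilin gene, from 3.95 ± 0.612 to 78.2 ± 39.9 FPKM (SD, n = 2). These genes moved with the hemocyte and muscle sheath markers, at relative medians of 2.63 and 3.58, and Pxn, their largest riser, is itself on the hemocyte list. Of 8 Hox genes, which set segment identity, 3 passed the filter on low values, Antp and Abd-B (control means 0.304 and 0.0406 FPKM) through the wh7 libraries alone, so their number says nothing of the group. abd-A rose from 1.13 ± 0.391 to 13.8 ± 3.001 FPKM. Genes induced by stress, picked after their values were seen, were each called higher, which says nothing of stress genes in general. The fixed heat shock and DNA damage lists went both ways. Beside Xrp1 and Thor, Gadd45 was at 5.58 and 33.7 FPKM in controls and wh7 (limma adjusted p = 0.0183). The JNK pathway genes kay and puc were at 12.1 and 64.8 FPKM (0.00909) and at 25.6 and 59.8 FPKM (0.0149). CG15784 (8.63 and 53.5 FPKM), Mmp1 (1.17 and 9.85 FPKM) and Ets21C (0.403 and 6.75 FPKM) were also called. Gadd45 and puc lost their calls without control 1, at 0.0585 and 0.0705 (ranges over the alternatives 0.00850 to 0.0585 and 0.00271 to 0.0705).

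Germline genes did not move as one. blanks, an RNA-binding protein gene with a known role in the male germline, rose 36.5-fold from 0.379 ± 0.0505 to 13.8 ± 0.334 FPKM (SD, n = 2), beside cona, ord, bgcn and RpS19b, whereas bam was at 24.9 ± 3.31 and 26.5 ± 3.91 FPKM (limma adjusted p = 0.709), vas at 179 ± 10.6 and 195 ± 0.591 FPKM (0.249) and AGO3 at 104 ± 5.08 and 112 ± 9.57 FPKM (0.449). nos, a gene of germ cell maintenance and embryonic patterning, fell 1.52-fold from 250.4 ± 5.02 to 165 ± 7.66 FPKM (limma adjusted p = 0.00874; call lost without control 1, adjusted p 0.00617 to 0.0513 over the alternatives). On chromosome X, dhd at 5312171 to 5313125 fell while its neighbour TrxT, a thioredoxin gene of the testis at 5310581 to 5311888 on the other strand, rose 7.40-fold from 0.374 ± 0.0442 to 2.77 ± 0.799 FPKM (limma adjusted p = 0.0137). The call of TrxT was lost without control 1 or control 2 and after quantile normalization, adjusted p 0.00966 to 0.339 over the alternatives. mt:lrRNA was at 28267 and 30529 FPKM in the controls and at 13114 and 15884 FPKM in wh7.

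The medians of the muscle sheath, hemocyte, follicle and fat body lists all lay above 0 in wh7. A lower share of germline RNA that raised all other cell types by the same factor would give equal medians only under 2 conditions. No list member may be expressed in the germline, and the log2(FPKM + 1) scale may not shrink the changes of low genes. The muscle and follicle medians differed by 2.17 on the log2 scale (two-sided permutation p = 0.00079, 100000 resamples). The permutation treats genes as independent, although the correlation estimated within the muscle list was 0.884, so its p is too small. The 2 lists did not rise alike, but germline expression of their members was not checked and the scale shrinks changes of low genes. The difference therefore does not decide whether the cell types rose by the same factor. A lower germline share, with equal or unequal rises of the other cell types, stays open, and unequal rises were not tested. Fat body carried over with the ovaries cannot be told apart from other sources: 1 of 6 fat body transcripts (Rfabg, at 5.34 and 11.7 FPKM) reached 10 FPKM in a wh7 library, but Lsp1beta, Lsp1gamma and Fbp1 among them are mainly larval and would stay low in adults in any case. All 6 were higher in both wh7 libraries than in both controls, such as Lsp2 at 0.0210 and 0.0652 FPKM in controls and 0.749 and 4.99 FPKM in wh7. More muscle tissue in the wh7 samples, from the ovarian sheath or the oviduct, cannot be told apart from a rise of muscle genes in the same amount of tissue, since both would raise the list together (82.4% of it, 14 of 17 genes, rose and lay within 1 log2 unit of their median), and an effect of wuho itself was not tested.

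Top3beta, next to wuho, was lower in wh7. Reads shared with wuho are argued against, since 0 exon bases lie in both genes, 109 bases separate them, and Top3beta kept a wh7 to control ratio of 0.201 against 0.0295 for wuho. A change of the X chromosome around wuho that lowers many neighbours cannot be told apart from the local spread: 16 tested neighbours within 50 kb had a median of -0.24 with 5 lower and 0 higher, and 8.54% of 1511 X windows of as many genes were as low, between the bounds of 5% and 50% set for the test. Top3beta lies on the minus strand and wuho on the plus strand, so their starts face each other across these 109 bases. A lesion or strain variant in that stretch or in Top3beta could also lower it, and this was not tested. Since Top3beta was lower as well, the comparison cannot assign the other changes in wh7 to wuho alone.

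Genes of the fourth chromosome were more often higher in wh7, with 35 of 80 higher and 4 lower, against 19.7% to 23.7% higher on the other chromosome arms. An extra copy is argued against by the 47 genes of at least 10 FPKM, whose median lay 0.19 above that of the other chromosomes (95% bootstrap interval 0.10 to 0.34, below the 0.58 of 3 copies against 2, if a copy adds in proportion). Low control expression is argued against as the whole cause, because 43.8% of the fourth chromosome genes rose and expression-matched sets gave 23.8% to 37.5%. Both the bootstrap and the matched sets treat genes of the same 4 libraries as independent. Their intervals leave out the spread between libraries and may be too narrow. The median of the matched sets, 30%, lay above the other arms, so expression level may account for part of the excess. A difference of cell types or of strain background between the flies may remain, and neither was tested for this chromosome.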
